A study of Rattus norvegicus with 3 samples.

How the data were processed

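Retinal RNA of 3 libraries, CTL, HIOP and HIOP_GSK, was analysed, with 1 library per group. Per the labels' protocols, retinas were flash frozen, RNA was extracted with Trizol, 3 µg of RNA per sample was depleted of ribosomal RNA, and directional libraries were prepared. The labels call the CTL retina untreated, while the protocol describes a sham group with a needle in the anterior chamber, and which of the 2 descriptions holds for the CTL library was not settled. The identity of the compound named GSK, its dose and the number of animals per library were not given in the sources used here.

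Each library's table gives a count and a TPM value (transcript abundance scaled to a fixed sum) for 32883 genes with Ensembl identifiers and symbols. Per the submitters' processing notes, STAR 2.5.4b, RSEM 1.3.1 and the rat genome build Rnor_6.0 were named, without the role of each. The deposited counts are whole numbers and are not normalized. They did not come from the same quantification as the deposited TPM: 19, 17 and 17 genes in CTL, HIOP and HIOP_GSK had a count of 0 and a TPM above 1, and 566, 545 and 503 genes had at least 20 counts and a TPM of 0. The strand setting of the counting was not given in the sources used here, so genes that overlap or lie antisense to others are uncertain, as are close paralogs such as the gamma crystallins, globins and histones. The analysis plan had assumed estimated counts to be rounded; the counts were already whole and were used as deposited. The deposited TPM values of each library sum to 1e+06, and the 3 most abundant entries took 30.2%, 33.5% and 30.5% of that sum, which affects TPM scaling, so TPM served as an alternative only. No genome annotation of Rnor_6.0 was used here, so no coordinates are given.

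Counts were scaled with the TMM factors of edgeR 4.0.16 (R 4.3.3), which were 1.000, 0.994 and 1.006 for CTL, HIOP and HIOP_GSK. Genes with a CPM of at least 1 in at least 1 library were kept, 15543 in all, 13368 of them with a gene symbol that is not an identifier or clone name. Log2 ratios were taken from log2 CPM with a prior count of 2, and a gene was counted as higher or lower at a ratio of at least 2-fold. No test across libraries was possible with 1 library per group, and no paired analysis either. Folds of named genes are ratios of scaled counts without a prior, with an exact Clopper-Pearson interval at 95% from the 2 counts. Against a count of 0, the fold is a lower bound computed with a floor of 3 counts per library, or 0.186, 0.175 and 0.197 CPM in CTL, HIOP and HIOP_GSK. Reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only.

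Before the data were examined, 48 gene lists were fixed for retinal cell types, glia, immune cells, neighbouring tissues, injury and stress pathways and housekeeping functions. They held 848 entries of 806 distinct genes, because some genes sit in more than 1 list. Of the distinct genes, 761 were matched by symbol and 7 by a synonym in the RefSeq gene table of the assembly GRCr8, used for names only. Another 38 were not analysed here, and 722 were kept. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean expression, and a list of at least 5 kept genes stood apart below percentile 2.5 or above 97.5. Named genes followed a rule fixed at the same time: per comparison, the 12 genes in each direction with the most extreme interval bound nearer to no difference, and per list the up to 4 members with the largest such bound in HIOP over CTL and in HIOP_GSK over HIOP. A gene named for 1 comparison may appear with its values in another, as Gfap and Ripk3 do, and Grifin was singled out after its values were seen. The values of some genes are not reported here.

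The functions were tested on simulated counts for HIOP over CTL, drawn from the real means and library sizes with 200 changed genes. With counting noise alone, over 15250 genes, 50.0% of the 2-fold and 99.0% of the 4-fold changes passed the 2-fold limit, 51 of 15050 unchanged genes passed it, and 95.2% of intervals held the true ratio. With an assumed coefficient of variation of 0.2 between animals, over 15318 genes, 50.5% and 97.0% passed, 452 of 15119 unchanged genes passed, and only 43.5% of intervals held the true ratio. Changes of exactly 2-fold lie on the limit, so such a share of them passes by construction. Of 2000 random lists of unchanged genes, 4.50% and 3.90% stood apart. These lists were drawn from genes simulated independently, so they do not describe lists of genes expressed together. Shares of genes moving back towards CTL, and overlaps of comparisons that share a library, were simulated in 20 draws each.

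Alternatives fixed in advance were total counts without TMM, DESeq2 1.42.0 size factors, the deposited TPM with a pseudocount of 0.5, no filter, a filter at CPM 5, prior counts of 0.5 and 10, scaling without mitochondrial and the 20 most abundant genes, genes with a symbol only, limits of 1.5-fold and 4-fold, a counting interval beyond 1, and list means. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.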

Results

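RNA was sequenced from the retina of Sprague-Dawley rats at postnatal day 60, after removal of ribosomal RNA, in 3 libraries. The CTL library came from retina labelled as untreated, although the treatment protocol describes sham-operated animals in which a needle was placed in the anterior chamber at 2.66 kPa. The HIOP library (high intraocular pressure) came from retina taken 12 h after the pressure in the eye had been held at 110 mmHg for 60 min, a procedure that stops retinal blood flow and is followed by reperfusion. The HIOP_GSK library came from the same procedure after an injection of a drug named only as GSK into the anterior chamber 24 h before ischemia. The labels describe no library from an eye injected with vehicle alone and do not say how many animals each library holds. The deposited counts summed to 16090064 in CTL, 17221510 in HIOP and 15132754 in HIOP_GSK. With 1 library per group, no difference has a replicate check and no p-value is given. Folds carry a 95% exact interval of the ratio of counts, which covers counting error only. Of 32883 genes, 15543 reached a CPM (count scaled to library size) of 1 in at least 1 library and were compared.

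The HIOP library was compared with CTL to describe the retina 12 h after ischemia. Inflammatory genes were far higher in HIOP, and most listed genes of Müller glia, ganglion cells, amacrine cells, cones and the surface epithelium of the eye were lower. All 24 kept cytokine and chemokine genes were at least 2-fold higher in HIOP, with a median log2 ratio of 6.13 (5.82 when the 10 genes without a count in CTL are set at their lower bound). The 9 neutrophil and monocyte genes that passed the filter on low counts were also at least 2-fold higher, with a median of 6.46 (5.86 with 6 genes at their bound). The list had 30 counts in CTL, so that filter kept mainly members with counts in an injured library. Without it, 10 of 14 members with a count were at least 2-fold higher and none at least 2-fold lower, with a median of 4.98. In total, 1399 genes were at least 2-fold higher and 1250 at least 2-fold lower, of 15543. This balance depended on the setting, and more genes were lower than higher with the deposited TPM (1064 higher and 1276 lower), without the filter (1950 and 2113) and at a limit of 1.5-fold (2508 and 2733).

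Among the chemokines, which attract leukocytes, Cxcl6 had 1 count in CTL and 5418 in HIOP, a ratio of 5094 (914 to 201251). Ccl2, which attracts monocytes, had 3 and 2758 counts, a ratio of 864 (295 to 4194). Cxcl1, a neutrophil attractant, was 566-fold higher (221 to 2079). Ccl20 and Cxcl2 had no count in CTL and were at least 358-fold and 251-fold higher in HIOP, and Ccl7 and Cxcl3 were at least 217-fold and 175-fold higher, against a floor of 3 counts per library. Csf3, the granulocyte growth factor, was at least 176-fold higher on the same floor, and so was the acute-phase gene Orm1, at least 230-fold. Il1b, which encodes the cytokine interleukin-1 beta, had 1 and 868 counts, a ratio of 816 (146 to 32273). Of the neutrophil genes, S100a8 was at least 127-fold, Il1r2 at least 68.0-fold and the chemokine receptor Cxcr2 at least 66.4-fold higher, and S100a9 was 231-fold higher (90.1 to 851). In the list of nuclear factor kappa B targets and adhesion genes, 12 of 18 members were at least 2-fold higher and none at least 2-fold lower, with a median of 2.16. Icam1, an adhesion molecule for leukocytes, was 21.3-fold higher (15.8 to 29.4), and Birc3 was 68.2-fold higher (31.1 to 187).

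The interferon response list had 24 of 25 members at least 2-fold higher in HIOP (median log2 ratio 2.68), among them Gbp2 at 112-fold (84.7 to 152) and Rsad2 at 29.6-fold (21.7 to 41.4). In the JAK-STAT3 list 16 of 20 members were at least 2-fold higher (median 2.01), with Socs3, a feedback inhibitor of cytokine signalling, at 102-fold (62.4 to 178). Of 19 reactive glia genes, 15 were at least 2-fold higher (median 3.23). Timp1 was 36.8-fold (29.2 to 47.0) and Lcn2 31.6-fold higher (27.6 to 36.2), whereas Gfap, the intermediate filament of reactive glia, had 580 counts in CTL and 642 in HIOP, a ratio of 1.04 (0.929 to 1.17). In the extracellular matrix and repair list 18 of 23 members were at least 2-fold higher and 2 at least 2-fold lower (median 2.34). Mmp3, a secreted matrix protease, had 1 and 4551 counts, a ratio of 4279 (768 to 169052). Of 23 immediate early genes, 16 were at least 2-fold higher (median 1.61), including the transcription factor genes Fosl1 at 681-fold (233 to 3304) and Junb at 14.8-fold (13.0 to 16.8).

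Lists tied to cell death had smaller medians. They share members with lists above, such as Birc3 with the nuclear factor kappa B list and Il1b with the cytokine list. In the necroptosis list 6 of 16 members were at least 2-fold higher in HIOP and none at least 2-fold lower (median 0.95). Ripk3, a kinase of that pathway, had 6 and 92 counts, a ratio of 14.4 (6.38 to 40.3). The pyroptosis and inflammasome list had 6 of 12 members at least 2-fold higher (median 0.76, which no longer stood apart from random lists without the filter on low counts, at 0.45), with Nlrp3 at 16.1-fold (9.74 to 28.6). In the apoptosis list 4 of 16 were at least 2-fold higher (median 0.38), including the death receptor gene Fas at 6.53-fold (4.59 to 9.54), although the mean of this list, 0.58, did not stand apart from random lists. Hmox1, which degrades heme, was 127-fold higher (87.3 to 193), and the median of the oxidative stress list was 0.65, with 7 of 17 members at least 2-fold higher and 1 at least 2-fold lower. Ribosomal protein genes had a median of 0.79 (6 of 26 at least 2-fold higher) and ribosome biogenesis genes one of 0.93 (8 of 19). The ribosomal protein list took 0.269% of counts in CTL and 0.477% in HIOP. Its members Rps6 and Rpl8 had 0 counts in both, so the counting of this family is uncertain. The microglia and macrophage list was mixed, with 6 of 16 members at least 2-fold higher and 3 at least 2-fold lower in HIOP, a median of 0.40 and a range from -1.99 to 3.17; its mean, 0.52, did not stand apart from random lists. The complement list had 8 of 15 members at least 2-fold higher (median 1.08), and C3 was 6.45-fold higher (5.46 to 7.67).

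Retinal cell type lists differed in how many members were lower in HIOP than in CTL. Of 14 Müller glia genes, 9 were at least 2-fold lower and 1 at least 2-fold higher (median log2 ratio -1.33). Kcnj10, the main potassium channel of these cells, had 312 counts in CTL and 12 in HIOP and was 27.7-fold lower (15.6 to 54.1), Rlbp1, a retinaldehyde-binding protein, was 5.97-fold lower (5.52 to 6.47), and the water channel gene Aqp4 was 4.996-fold lower (4.59 to 5.44). In the ganglion cell list 10 of 15 genes were at least 2-fold lower (median -1.16). Nrn1 was 3.34-fold lower (2.74 to 4.09) and the transcription factor gene Pou4f2 3.38-fold lower (2.27 to 5.17), while Gap43, a growth cone protein, was 4.39-fold higher (3.90 to 4.96). In the amacrine cell list 7 of 12 were at least 2-fold lower (median -1.19), with Chat, the enzyme of acetylcholine synthesis, at 6.89-fold lower (4.92 to 9.86). In the cone list 8 of 13 were at least 2-fold lower (median -1.09), with Arr3, cone arrestin, at 7.69-fold lower (6.89 to 8.61). The rod list had a median of -0.09, and none of its 14 genes was 2-fold different in either direction. Bipolar cell genes had a median of -0.53 with 1 of 13 at least 2-fold lower. Glutamate and GABA receptor genes had a median of -0.82 (8 of 23 at least 2-fold lower), and sodium and potassium channel genes one of -0.88 (5 of 17).

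Genes of neighbouring tissues also differed between these libraries. In the corneal and surface epithelium list 7 of 9 genes were at least 2-fold lower in HIOP (median log2 ratio -3.58, also with the 1 gene without a count at its bound). Krt12, the keratin of corneal epithelium, had 1950 counts in CTL and 56 in HIOP and was 37.0-fold lower (28.4 to 49.2), Krt5 was 28.4-fold lower (20.04 to 41.5), and Kera, with 59 and 0 counts, was at least 20.9-fold lower. Pigment epithelium genes had a median of -1.31 (8 of 11 at least 2-fold lower), and Rpe65, the isomerase of the visual cycle, was 4.28-fold lower (3.72 to 4.92). In the lens list 17 of 18 genes were at least 2-fold higher (median 1.59), and the lens list took 0.130% of counts in CTL and 0.374% in HIOP. The gamma crystallin genes of this list, such as Crygd, 8.96-fold higher (7.93 to 10.1), are close paralogs, so the split of counts among them is uncertain. The 4 kept red blood cell genes were all at least 2-fold higher in HIOP (median 1.3), but with the deposited TPM the log2 ratios of Hbb, Alas2 and Slc4a1 were 0.90, 0.76 and 0.66, below 2-fold. Without the lens, surface epithelium, pigment epithelium, red blood cell and cell cycle lists, 1374 genes were at least 2-fold higher and 1235 at least 2-fold lower. Only the list members were taken out, so the drop is fixed by their own calls and other genes of these tissues stay in.

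The median of 34 of the 45 lists with at least 5 kept genes lay outside the central range of 10000 random lists matched on mean expression, 21 above and 13 below, where 2.25 would by the draw alone. Random lists hold unrelated genes, so a list of genes expressed together stands apart more readily, and the percentile describes these libraries rather than the conditions. Some lists share members, so their results are not independent of each other.

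**Figure D1:**
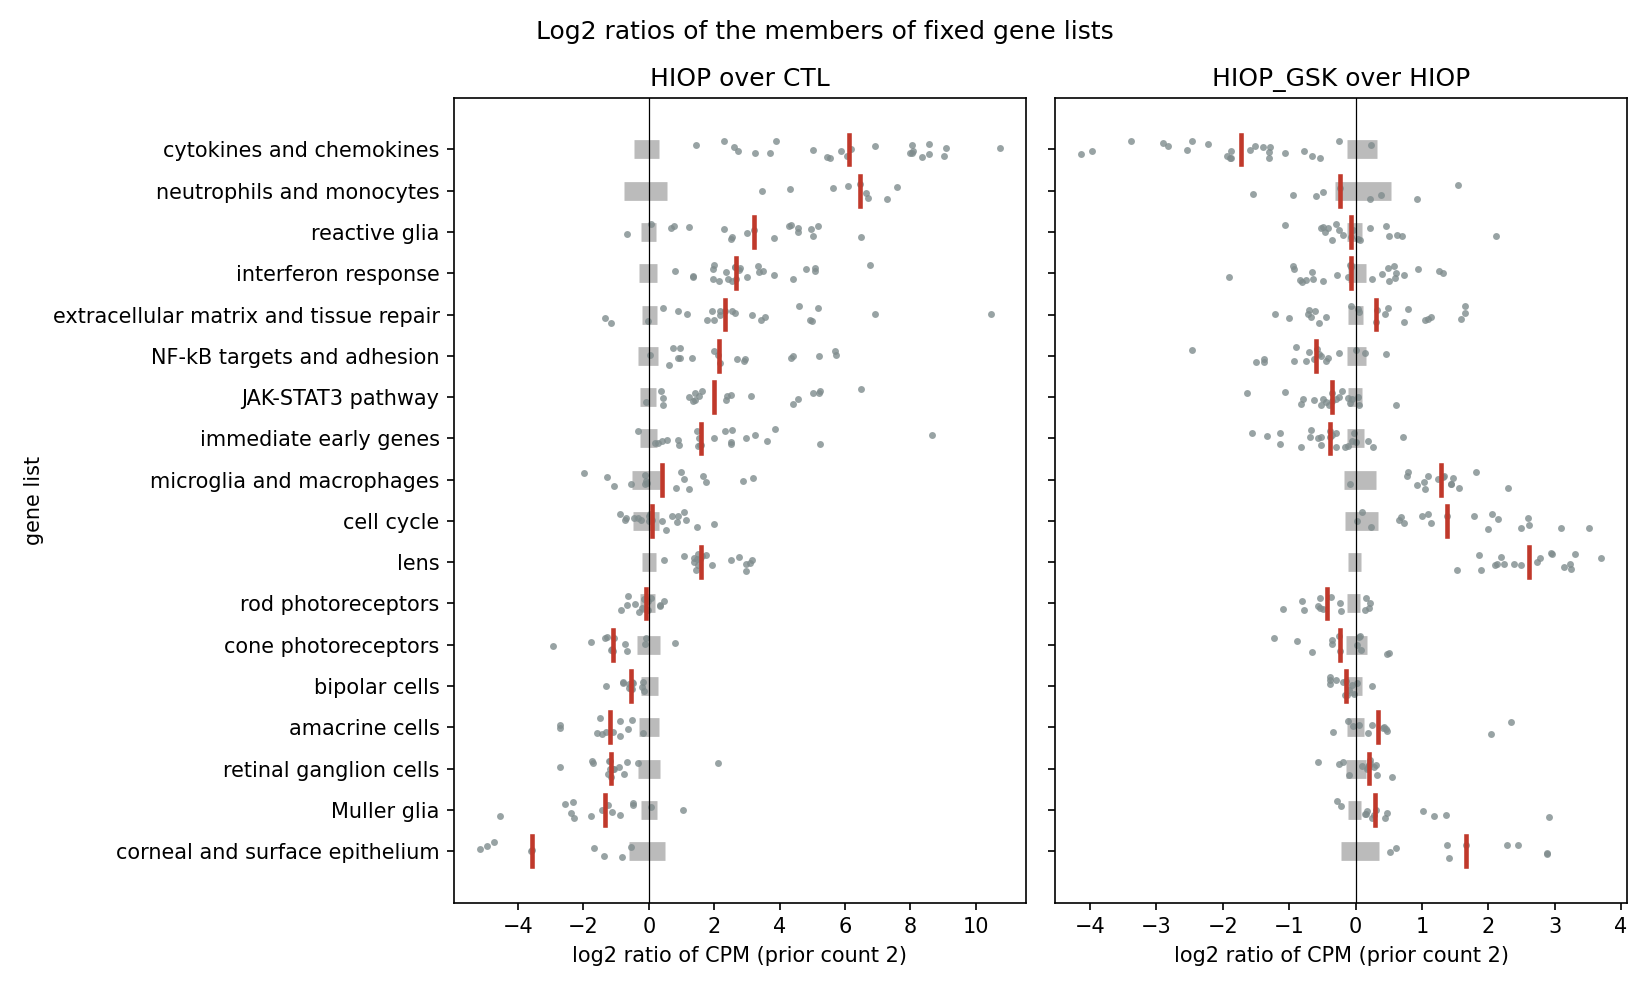
Log2 ratios of CPM of the kept members of 18 gene lists, for HIOP over CTL on the left and HIOP_GSK over HIOP on the right. Each grey point is a gene, each red line the list's median and each grey bar the central 95% of the medians of 10000 random lists, and the cytokine list sits at a median of 6.13 on the left and -1.73 on the right.

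The HIOP_GSK library was compared with HIOP to describe the injured retina with and without the drug. Most chemokine and cytokine genes were lower in HIOP_GSK, and most listed genes of the lens, the cell cycle and microglia were higher. Of the 24 cytokine and chemokine genes, 19 were at least 2-fold lower and none at least 2-fold higher (median log2 ratio -1.73). Cxcl6 was 17.6-fold lower (15.6 to 19.99), Csf3 16.6-fold (11.5 to 24.9), Ccl20 10.6-fold (8.59 to 13.2) and Cxcl1 7.51-fold lower (6.64 to 8.52). In total, 709 of 15543 genes were at least 2-fold higher and 263 at least 2-fold lower.

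Cxcl10, an interferon-induced chemokine, was 7.17-fold lower in HIOP_GSK (6.02 to 8.60), and Ptx3, a soluble pattern recognition protein, was 14.7-fold lower (12.0 to 18.1). Il1b was 1.71-fold lower (1.52 to 1.92), within the 2-fold limit. The list of nuclear factor kappa B targets and adhesion genes had a median of -0.60, with 4 of 18 members at least 2-fold lower, among them the endothelial adhesion genes Sele at 5.75-fold (4.08 to 8.33) and Vcam1 at 2.60-fold lower (2.40 to 2.82). Immediate early genes had a median of -0.38 (4 of 23 at least 2-fold lower), and Egr1 was 2.53-fold lower (2.42 to 2.64). In the JAK-STAT3 list 2 of 20 were at least 2-fold lower (median -0.35), with Cish at 3.12-fold lower (2.82 to 3.45). The interferon list had a median of -0.08 with members on both sides: Gbp5 was 3.76-fold lower (3.23 to 4.40), and Ifit1 was 2.51-fold higher (2.02 to 3.13). Fas, with 250 counts in HIOP and 65 in HIOP_GSK, was 3.42-fold lower (2.59 to 4.56). The medians of the necroptosis and apoptosis lists were -0.15 and 0.01, and Ripk3 had 92 and 96 counts. The pyroptosis and inflammasome list had a median of 0.26, with 2 of 12 members at least 2-fold higher and none at least 2-fold lower.

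The 9 neutrophil and monocyte genes had a median of -0.23 in HIOP_GSK over HIOP, within the range of the random lists, with Trem1 at 3.05-fold lower (2.02 to 4.75) and Csf3r, the receptor for granulocyte growth factor, at 2.92-fold higher (2.58 to 3.30). Of 16 microglia and macrophage genes, 12 were at least 2-fold higher and none at least 2-fold lower (median 1.28), where the same list had been mixed in HIOP over CTL. Cx3cr1, the fractalkine receptor, was 5.25-fold (3.44 to 8.28) and Csf1r, the receptor for macrophage growth factor, 3.55-fold higher (3.05 to 4.14). Complement genes had a median of 0.92 (7 of 15 at least 2-fold higher), including C5ar1 at 2.94-fold (2.22 to 3.93). In the extracellular matrix list 6 of 23 were at least 2-fold higher and 2 at least 2-fold lower (median 0.32), with Fn1, fibronectin, at 3.15-fold (2.97 to 3.34) and Spp1, osteopontin, at 3.00-fold higher (2.71 to 3.34).

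All 18 lens genes were at least 2-fold higher in HIOP_GSK than in HIOP (median log2 ratio 2.62), and the lens list took 1.65% of counts, against 0.374% in HIOP. Lgsn was 13.1-fold (11.5 to 14.9), Crygb 9.88-fold (9.40 to 10.4), Bfsp1, a lens filament protein, 9.46-fold (8.46 to 10.6) and Mip, the lens water channel, 7.81-fold higher (7.19 to 8.50). Of 9 corneal and surface epithelium genes, 7 were at least 2-fold higher (median 1.66), with Krt5 at 7.81-fold (5.40 to 11.6) and Krt12 at 5.002-fold (3.73 to 6.81). In the cell cycle list 12 of 19 genes were at least 2-fold higher and none at least 2-fold lower (median 1.37). Top2a, a topoisomerase of dividing cells, was 12.1-fold higher (8.67 to 17.2) and Mki67, a proliferation marker, 8.78-fold (6.96 to 11.2). Replication-dependent histone genes had a median of 0.80, with 7 of 17 at least 2-fold higher and 1 at least 2-fold lower. Fam111a had 12 counts in HIOP and 225 in HIOP_GSK and was 21.1-fold higher (11.8 to 41.4). Wbp11 had counts of 0, 0 and 76 in CTL, HIOP and HIOP_GSK and was at least 28.5-fold higher on counts, but its deposited TPM was 0 in all 3 libraries, and so was that of Mast4, with 0, 27 and 0 counts. Without the lens, surface epithelium, pigment epithelium, red blood cell and cell cycle lists, 672 genes were at least 2-fold higher and 261 at least 2-fold lower. Again only list members were left out, so these totals say nothing about other genes of those tissues.

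Among retinal genes, Gfap was 4.33-fold higher in HIOP_GSK than in HIOP (3.97 to 4.73), whereas the reactive glia list as a whole had a median log2 ratio of -0.07. The Müller glia list had a median of 0.30, with 4 of 14 members at least 2-fold higher, among them Kcnj10 at 8.72-fold (4.76 to 17.5) and Aqp4 at 2.28-fold (2.08 to 2.51). The amacrine list had a median of 0.33, with 2 of 12 genes at least 2-fold higher, and Chat was 4.28-fold higher (3.00 to 6.22). Ganglion cell genes had a median of 0.20, and none of the 15 was 2-fold different. The rod list had a median of -0.43, below the random lists, with 13 of 14 genes within 2-fold and a range from -1.09 to 0.22. The 1 gene past 2-fold was Gnat1, rod transducin, at 2.13-fold lower (2.11 to 2.16). The cone and bipolar cell lists also stood below the random lists, with medians of -0.23 and -0.15. Common reference genes stood above the random lists with a median of 0.18, so shifts of this size were not particular to cell type lists. Hmox1 was 1.65-fold higher (1.58 to 1.72). The medians of 33 of 45 lists stood outside the range of the random lists, 21 above and 12 below.

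Of the 1399 genes at least 2-fold higher in HIOP than in CTL, 110 had a level in HIOP_GSK at or below the midpoint between HIOP and CTL on the log2 scale, a share of 7.86% (95% exact binomial interval 6.51 to 9.40). Of the 1250 genes at least 2-fold lower in HIOP, 302 were at or above the midpoint, a share of 24.2% (21.8 to 26.6). The HIOP library enters both differences, so chance values there move such genes towards CTL. Simulated libraries in which HIOP_GSK had the means of HIOP gave shares of 1.39% and 3.72% with counting noise alone, 9.27% and 14.4% with an assumed coefficient of variation between animals of 0.2, and 27.9% and 35.9% with 0.4. The first share lay below the value simulated with 0.2, and the second between those with 0.2 and 0.4. The simulation took the observed counts as true means and added noise to them again, so its shares are a rough guide only. With the deposited TPM the first share was 12.6%, and without the filter on low counts 18.7%.

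**Figure D2:**
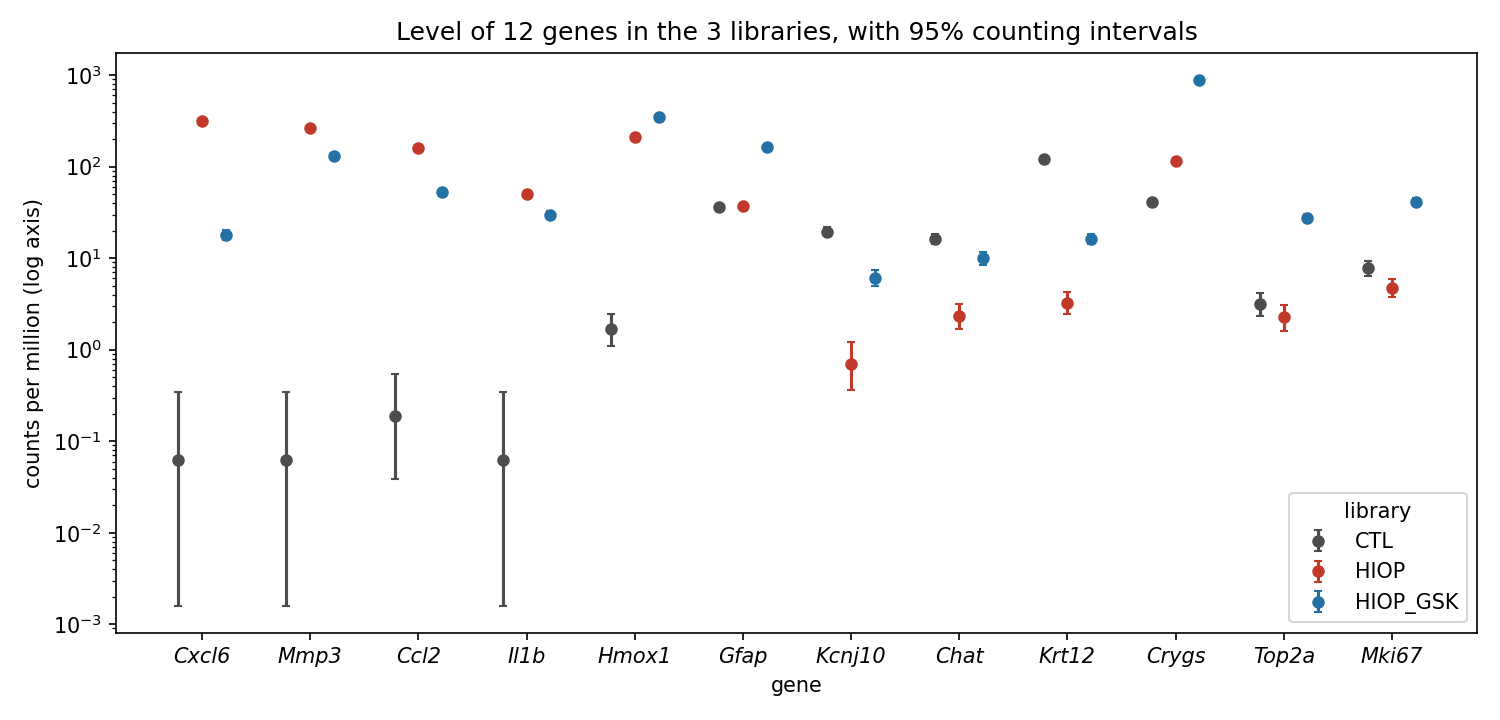
CPM of 12 genes in the CTL, HIOP and HIOP_GSK libraries, 1 point per library on a log axis, with 95% exact Poisson intervals that cover counting error only. Cxcl6 stood at 0.0621 CPM in CTL, 316 in HIOP and 17.9 in HIOP_GSK, and Crygs stood at 40.6, 115 and 884.

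The HIOP_GSK library was also set against CTL, to describe the drug-treated injured retina beside the uninjured one. Inflammatory genes remained far above CTL, and most listed cone and ganglion cell genes were below it. The 9 neutrophil and monocyte genes past the filter had a median log2 ratio of 6.68 (6.28 with 6 genes at their bound), and without the filter 11 of 14 were at least 2-fold higher and 1 at least 2-fold lower (median 4.61); 21 of 24 cytokine and chemokine genes were at least 2-fold higher (median 4.11, the same with 9 genes at their bound). Hmox1 was 210-fold higher than in CTL (144 to 319), S100a8 at least 108-fold, Acod1, an enzyme of activated macrophages, at least 115-fold, and Slpi, a secreted protease inhibitor, 151-fold (82.1 to 317). In total, 1623 genes were at least 2-fold higher and 983 at least 2-fold lower.

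Cone genes had a median of -1.31 in HIOP_GSK over CTL (8 of 13 at least 2-fold lower and 1 at least 2-fold higher), with Opn1mw, the middle-wavelength opsin, at 8.19-fold (6.603 to 10.3) and Arr3 at 7.32-fold lower (6.54 to 8.22). The ganglion cell list had a median of -1.0 (8 of 15 at least 2-fold lower and 1 at least 2-fold higher) and the Müller glia list one of -0.98 (7 of 14 at least 2-fold lower and 1 at least 2-fold higher). Hhatl, with 249, 12 and 14 counts in CTL, HIOP and HIOP_GSK, was 16.8-fold lower than in CTL (9.83 to 31.2). Microglia genes had a median of 1.61 (11 of 16 at least 2-fold higher), pyroptosis and inflammasome genes 1.62 (10 of 12), cell cycle genes 2.08 (14 of 19) and lens genes 4.46 (all 18). The medians of 35 of 45 lists stood outside the range of the random lists.

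Both differences from CTL use the same CTL library. Across genes, which are not independent replicates, the log2 ratios HIOP over CTL and HIOP_GSK over CTL had a correlation of 0.856, against 0.497 in simulated unchanged groups with counting noise alone. Their covariance was 0.838, against 0.0194 simulated with counting noise and 0.105 with an assumed variation of 0.2, a difference of 0.819 and 0.733. At least 2-fold higher in both were 1141 genes, where simulated unchanged groups gave 7.10 and 59.0 and independent lists would share 146. At least 2-fold lower in both were 646 genes, against 3.05 and 29.9 simulated and 79.1 for independent lists. With 1 CTL library the controls could not be split, and part of the excess may come from the shared library.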

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

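The tests in this part on the neutrophil, reactive glia and non-crystallin lens genes, and the weighing of 1 library per group, were chosen only after the result was seen; those on the second lens and epithelial lists were fixed before their values were seen.

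Among the named genes, 6 were at least 2-fold on opposite sides of CTL in the HIOP and HIOP_GSK libraries. The difference between the libraries was not tested, because each is a single library. The log2 ratios over CTL were 2.49 in HIOP and -3.25 in HIOP_GSK for Rbp7, 1.79 and -3.58 for Bpifa6, 1.36 and -3.02 for Sptlc3, and 2.35 and -1.55 for Sdr16c6. They were -1.27 and 1.04 for the microglial receptor gene Cx3cr1 and -1.66 and 1.23 for the basal epithelial keratin gene Krt14. Several rest on few counts: in CTL, HIOP and HIOP_GSK, Rbp7 had 17, 111 and 0, Bpifa6 60, 226 and 3, Sptlc3 100, 276 and 10, and Sdr16c6 10, 63 and 2, while Cx3cr1 had 64, 27 and 126 and Krt14 40, 12 and 91. Over all 15543 genes, 10 were higher in HIOP and lower in HIOP_GSK, and 7 the other way.

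Cytokine and chemokine genes were lower in HIOP_GSK than in HIOP (median log2 ratio -1.73). Fewer myeloid cells would lower neutrophil and monocyte genes alike, but their median was -0.23 and the lowest of the 9 stood at -1.55. Their members went both ways, with 1 of the 9 at least 2-fold higher and 1 at least 2-fold lower. Without the filter on low counts, the median was -0.36 over 14 genes, with 3 at least 2-fold higher and 3 at least 2-fold lower. The quartile requirement used for the second lists below was not applied here. Dilution by RNA of other tissue would lower reactive glia genes too. Their median without the cytokine gene Lif was -0.0537, and the lowest of 18 stood at -0.52. Most reactive glia genes differed between HIOP and CTL, so they are no fixed reference. The rod, cone and bipolar lists had medians of -0.43, -0.23 and -0.15. The Müller glia, amacrine, ganglion and horizontal cell lists stood at 0.30, 0.33, 0.20 and 0.13. The neutrophil and reactive glia values argue against those explanations as the whole cause, but a smaller dilution is not excluded. With 1 library per group, a difference between animals, in timing or from the injection itself cannot be told apart from an effect of the drug, which stays open and untested.

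Lens genes were higher in HIOP_GSK (median 2.62 over HIOP). Lens tissue carried into the library may be the source, but the prediction made in advance was not met: a second list of 9 kept lens genes had a median of 0.33, below the 0.5 set as evidence against it. Its members went both ways, with quartiles of -0.05 and 2.15 and the highest value, 2.55, for Grifin, and 4 of 9 were at least 2-fold higher, with all 9 at 1 CPM or more in CTL. Because of that spread, by a quartile requirement added after the values were seen, lens tissue was left open, neither supported nor excluded. The level in CTL reached 333 CPM for Tdrd7, whose log2 ratio was -0.05, so the second list may not read out lens tissue alone. A response of crystallin genes alone is argued against, since the 5 other lens genes of the first list had a median of 2.96 and a lowest value of 2.39.

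Surface epithelium genes were lower in HIOP than in CTL (median -3.58). Unequal carry-over of epithelium from the front of the eye may be the source, and the prediction made in advance, a median of -1 or less in a second epithelial list, was narrowly met at -1.06. The same quartile requirement left it open as well: 11 of 22 genes were at least 2-fold lower, but the quartiles were -1.93 and 0.27, and all 22 reached 1 CPM in CTL. No biological explanation was tested.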

How the results depend on the processing

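The TPM rescaling and the removal of tissue lists were chosen after seeing the data. No named gene past 2-fold took the opposite direction under the alternatives fixed in advance, and other genes were not checked for this. The filters and the choice of genes with a symbol leave a gene's own ratio unchanged. Other priors and near-equal scaling factors could not turn a 2-fold difference either, so only the deposited TPM could have done so. Of the named genes, Wbp11 and Mast4 stood at 0 with the deposited TPM. For HIOP over CTL, the deposited TPM gave 1064 genes higher and 1276 lower, turning the balance, and the rescaled TPM gave 1170 and 1076. Without a filter, the counts of genes higher and lower in HIOP over CTL, higher and lower in HIOP_GSK over HIOP, and higher and lower in HIOP_GSK over CTL were 1950, 2113, 1448, 711, 2534 and 1826, and the shares moving back towards CTL were 18.7% and 29.3%. At CPM 5 the same values were 997, 773, 336, 114, 1055 and 594, and 6.12% and 16.8%; more or fewer genes enter by construction. With a prior count of 10, 153 genes were lower in HIOP_GSK over HIOP and the second share was 19.0%, by shrinkage of low counts. At 1.5-fold the counts higher and lower were 2508 and 2733 for HIOP over CTL, 1504 and 749 for HIOP_GSK over HIOP, and 2739 and 2585 for HIOP_GSK over CTL, and the first share was 11.7%. At 4-fold they were 528 and 207, 145 and 46, and 690 and 135, with shares of 6.06% and 31.9%. With the deposited TPM the shares were 12.6% and 20.9%, and with the rescaled TPM 12.6% and 21.8%; the cause was not tested. Total counts, DESeq2 size factors, a prior of 0.5, other scaling genes, symbols only and the counting interval kept all counts within 1.5 times and both shares within their binomial intervals. For HIOP over CTL, HIOP_GSK over HIOP and HIOP_GSK over CTL, 33 to 34, 27 to 34 and 34 to 37 lists stood apart over the alternatives that kept 45 lists large enough, with the low ends by the mean. Without the filter they were 33, 34 and 36 of 47, and without the tissue lists 30, 27 and 31 of 41, fewer by construction. No list whose median stood apart changed sign in its median under the settings above or in its mean. The size of some medians depended on the setting: over the settings, the list of neutrophils and monocytes moved from 6.46 to between 3.99 (TPM) and 8.08 (prior count 0.5) for HIOP over CTL, and from 6.68 to between 4.61 (no filter) and 7.12 (prior count 0.5) for HIOP_GSK over CTL. The list of cytokines and chemokines moved from 6.13 to between 4.67 (prior count 10) and 7.69 (prior count 0.5) for HIOP over CTL, and from 4.11 to between 3.26 (prior count 10) and 5.76 (prior count 0.5) for HIOP_GSK over CTL. The corneal and surface epithelium list moved from -3.58 to -2.62 at CPM 5 for HIOP over CTL. By the mean, 32 of 34, 25 of 33 and 32 of 35 lists stood apart as well, and those lost included the microglia and apoptosis lists in HIOP over CTL and the ganglion cell and necroptosis lists in HIOP_GSK over HIOP. The pyroptosis list lost its place without the filter in HIOP over CTL, and the pericyte list at CPM 5 in HIOP_GSK over HIOP. With the deposited TPM, the visual cycle list no longer stood apart in HIOP over CTL, nor did the pericyte, ferroptosis, channel, cholesterol, ribosomal protein and ribosome biogenesis lists in HIOP_GSK over HIOP. With the deposited TPM, 170 of 187, 182 of 191 and 24 of 24 named genes stayed on the same side of the 2-fold limit. No paired analysis was possible because each group holds 1 library. Depth limits genes near 3 counts, and the lack of replicates limits all genes. A count of 0 need not mean low expression. The ribosomal protein gene Rps6 and the reference gene Hprt1 had counts of 0, 0 and 0 in CTL, HIOP and HIOP_GSK, and the cause was not tested.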

Other observations

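Nuclear oxidative phosphorylation genes had median log2 ratios of 0.12 for HIOP over CTL and 0.02 for HIOP_GSK over HIOP, and hypoxia response genes -0.13 and 0.25, although Angptl4, a secreted lipase inhibitor, was 30.0-fold higher in HIOP (20.5 to 45.8). Circadian clock genes had medians of -0.54 and 0.32, with Dbp 2.24-fold lower in HIOP (2.09 to 2.39). Pericyte and smooth muscle genes had medians of -0.97 and 0.27, with Acta2 3.74-fold lower in HIOP (3.24 to 4.33), and vascular endothelium genes -0.15 and 0.60. Among genes often used as references, B2m was 3.29-fold (3.09 to 3.51) and Actb 1.91-fold higher in HIOP (1.86 to 1.95).

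Medians for HIOP over CTL and for HIOP_GSK over HIOP were -0.32 and 0.13 for horizontal cells, 0.59 and 0.14 for ferroptosis and iron, 0.38 and 0.01 for the heat shock response, and 0.32 and -0.36 for the unfolded protein response. They were 0.34 and -0.03 for p53 targets, -0.62 and -0.10 for synaptic vesicle genes, -0.32 and 0.41 for the visual cycle, and 0.03 and -0.13 for cholesterol synthesis. Glycolysis genes had medians of -0.16 and 0.24, mitochondrially encoded genes -0.18 and -0.16, common reference genes 0.11 and 0.18, histones -0.01 and 0.80, the 2 kept lymphocyte genes -0.46 and 0.22, and the 3 kept sex-linked genes 0.30 and -0.06.

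The red blood cell genes were highest in HIOP: the more abundant of the entries named Hba-a2 had 1524, 3762 and 1486 counts in CTL, HIOP and HIOP_GSK, and Hbb had 531, 1140 and 568. Aox4 had 23, 48 and 0 counts. Of the kept genes, 731 had a deposited TPM of 0 in all 3 libraries.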
